A study of Homo sapiens with 6 samples.

How the data were processed

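RNA-seq of total RNA was measured in 6 libraries of human glutamatergic neurons derived from induced pluripotent stem cells, 3 treated with a non-targeting siRNA and 3 with an siRNA against G3BP2. Per the labels' protocols, RNA was isolated on columns and libraries were made with a stranded kit that removes ribosomal RNA. The authors deposited whole-number counts per Ensembl gene, with no normalization. Per the submitters' processing notes, bcl2fastq, Trimmomatic 0.32, STAR 2.5.1b, RSEM and DESeq2 1.28.1 were used with GRCh38. The role of each tool, the counting step, its use of strand and the annotation release are not given in the sources used here. Each of the 46355 gene identifiers is in GENCODE 29, which gave symbols and GRCh38 coordinates. Every deposited count is even (0 odd values), as when both mates of a read pair are counted. Doubled counts understate counting noise in a count model, so a fit of halved counts was added after seeing the data.

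Totals ran from 87507504 to 127990746 counts per library, and 3947 genes had 0 counts in all 6. Intervals cover the spread between libraries as fitted, and reads without molecular identifiers are not independent molecules. Replicates of a group were compared before averaging, on halved counts. Over genes with enough counts the chi-square per degree of freedom was 12 to 68.6 in the 6 pairs within groups, more than counting noise alone would give. Abundant RNAs weigh most in this value, and the share of 7SL RNA ran from 2.09 to 5.55% of counts. It therefore does not measure the spread of a typical gene or show that libraries are separate cultures. Each library was kept as a replicate because the labels number it as one.

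Groups were taken from the treatment in the labels, and columns from the descriptions. The comparison was the G3BP2 siRNA against the non-targeting siRNA, with no covariate. Genes were filtered with filterByExpr, which left 25294 genes, 15269 of them protein coding. Library sizes were scaled by TMM, and genes were tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error was the absolute log2 fold change divided by the square root of F. CPM values are TMM scaled.

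A set of 33 gene lists, 24 of pathways and 9 of cell type markers, was fixed before the data were examined, as were the groups, the main test and the other settings except 2 named as added. Of these, 31 had at least 5 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 31 lists. With an estimated correlation, or with fry, 0 of the 31 lists were called. The genes named in the text were G3BP2, G3BP1, protein-coding genes that passed the test with at least 1 CPM and groups that did not overlap (the 12 largest increases, the 12 largest decreases and the 6 smallest p-values), and up to 4 members of each list with the smallest p. Genes used to tell sex were never named. Genes outside that rule are said to be chosen after their values were seen.

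The test was run on simulated counts with the means and library sizes of these libraries. Their spread followed the fitted trend with expression, without the spread of single genes around it or correlation between genes. Of 24459 simulated genes tested, 50 were changed at each of 4 folds, and 14, 36, 62 and 90% were called at 1.25, 1.5, 2 and 4-fold. Of 24216 unchanged genes, 7 were called, and a list shifted by 0.3 on the log2 scale was called with 0 others.

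The other settings tried were RLE and upper quartile factors, DESeq2 1.42.0, limma voom, no filter except 1 count, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out, and for lists an estimated correlation, fry and ranks. A fit with the 7SL share as a covariate was added after seeing the data. It used the counts of 405 7SL genes and pseudogenes. For the closing observations, 7-mers in the longest annotated 3' UTR of each gene were scored against the ranked signed statistic of 11498 genes, after regression on 3' UTR length, GC content and expression, with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.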

Results

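RNA-seq profiles were compared between human neurons treated with a small interfering RNA (siRNA) against G3BP2 and the same neurons treated with a non-targeting siRNA. The cells were commercial glutamatergic neurons (iCell GlutaNeurons) differentiated from human induced pluripotent stem cells. An siRNA is a short duplex that directs the cleavage of a matching transcript, and a non-targeting siRNA is designed to match none. G3BP2 is an RNA-binding protein of stress granules, the cytoplasmic assemblies of untranslated mRNA and protein that form under stress. The series concerns the interaction of G3BP2 with the microtubule-associated protein tau. The comparison asked which transcripts differ in neurons when G3BP2 is reduced. Each group held 3 libraries of total RNA depleted of ribosomal RNA. The non-targeting libraries held 115011450, 106847670 and 123149840 counts, and the G3BP2 siRNA libraries held 127120668, 127990746 and 87507504. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

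G3BP2 fell to 19.5% ± 3.72 (SD, n = 3) of its non-targeting mean. G3BP2 (ENSG00000138757) lies on the minus strand of chromosome 4, from 75642782 to 75724525 in GRCh38. Its level was 851.4, 773.9 and 760.3 CPM, the count scaled to the size of the library, in the non-targeting libraries. In the G3BP2 siRNA libraries it was 124.6, 183.7 and 156.2 CPM, so each of the 6 libraries matched its label. The fitted log2 fold change was -2.36 (SE 0.15, 95% interval -2.72 to -1.996), a 5.14-fold decrease with adjusted p = 0.0434 in the edgeR quasi-likelihood test. That adjusted p lay near the threshold although the groups were far apart, and DESeq2 gave 1.3e-95 for the same gene. The edgeR adjusted p was 0.0511 with RLE factors, 0.134, 0.295 and 0.389 without non-targeting replicate 1, 2 and 3, and 0.345 without G3BP2 siRNA replicate 3.

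The paralog G3BP1, a core protein of stress granules that shares the domain structure of G3BP2, was measured at 196.6 ± 13.3 CPM (SD, n = 3) with the non-targeting siRNA. With the G3BP2 siRNA its level was 204.3 ± 5.12 CPM (SD, n = 3). G3BP1 (ENSG00000145907; chromosome 5, 151771045 to 151812785, plus strand) had a log2 fold change of 0.06 (SE 0.06, 95% interval -0.07 to 0.18; edgeR adjusted p = 0.998). A difference was not detected, and the interval excludes an increase above 0.18 on the log2 scale. Its first part overlaps ATOX1 on the opposite strand.

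**Figure D1:**
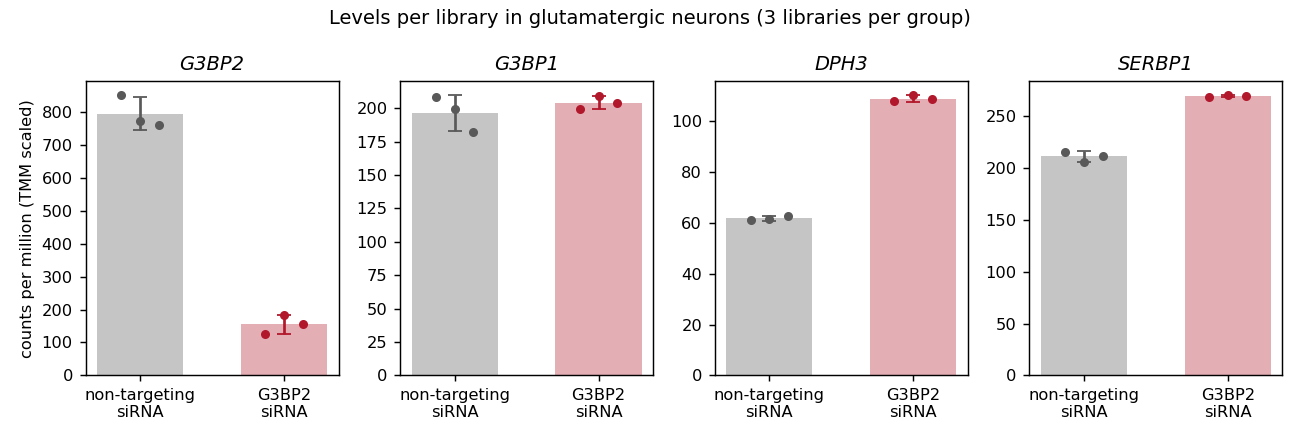
CPM of G3BP2, G3BP1, DPH3 and SERBP1 in the 3 libraries of each group. Points are libraries, bars are group means and error bars are 1 SD; the G3BP2 siRNA libraries sit between 124.6 and 183.7 CPM for G3BP2, and between 107.7 and 110.2 CPM for DPH3 against 61.05 to 62.81 CPM in the non-targeting libraries.

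Apart from G3BP2, 2 genes passed the test, and both were higher with the G3BP2 siRNA than with the non-targeting siRNA. DPH3, which encodes a protein of the diphthamide synthesis pathway that modifies translation elongation factor 2, rose from 61.7 ± 0.944 to 108.8 ± 1.23 CPM (SD, n = 3 each). Its log2 fold change was 0.82 (SE 0.05, 95% interval 0.71 to 0.93; edgeR adjusted p = 7.82e-06), a 1.76-fold increase. DPH3 (ENSG00000154813) lies on the minus strand of chromosome 3, from 16257978 to 16264972. SERBP1, which encodes an mRNA-binding protein that associates with ribosomes, rose from 211.3 ± 4.85 to 269.6 ± 1.07 CPM (SD, n = 3 each). Its log2 fold change was 0.35 (SE 0.05, 95% interval 0.25 to 0.46; edgeR adjusted p = 0.0434), or 128% of the non-targeting mean. SERBP1 (ENSG00000142864) lies on the minus strand of chromosome 1, from 67407810 to 67430415. Both genes have processed copies elsewhere in the genome, and how reads shared with such copies were counted is not given in the sources used here. SERBP1 lost its call with RLE factors (adjusted p = 0.0511), with upper quartile factors (0.153) and with the stricter filter (0.0525). It also lost it without non-targeting replicate 2 (0.589) and without G3BP2 siRNA replicate 1, 2 or 3 (0.483, 0.522 and 0.784).

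In all, 3 of 25294 genes tested changed, 2 of them higher and 1 lower, and 2 of the 3 changed at least 1.5-fold. At an unadjusted p under 0.05 there were 1211 genes, where 5% of the genes tested is 1265. The groups did not overlap for 2840 genes (11.2%), where chance gives 10%. Among the 9530 genes at 10 CPM or more, the 95% interval reached a median of 0.151 on the log2 scale to either side, which is 1.11-fold. In simulated libraries of this depth, with spread set by the fitted trend alone, 13 of 14 such genes changed 1.5-fold were called (92.9%). The simulation left out the spread of single genes around the trend and correlation between genes. Power in the real libraries may therefore be lower: G3BP2 itself, 5.14-fold lower, had an edgeR adjusted p of 0.0434. The count of genes depended on single libraries: it was 18 without non-targeting replicate 1, and 1 without non-targeting replicate 2 or without G3BP2 siRNA replicate 3. DESeq2 called 19 genes, 12 higher and 7 lower, which included the 3. Without a filter on low counts edgeR called 50. The genes that follow were chosen after their values were seen, from the DESeq2 calls. FEZ1, a kinesin adaptor in axonal transport, measured 211.8 ± 7.44 and 267.9 ± 4.80 CPM (edgeR adjusted p = 0.0732). POLE3, a subunit of DNA polymerase epsilon, measured 25.4 ± 1.002 and 34.7 ± 1.41 CPM (0.0932). SYNDIG1, a regulator of AMPA receptors at synapses, measured 42.7 ± 8.27 and 67.9 ± 4.74 CPM (0.824). The nuclear receptor gene ESRRG measured 23.8 ± 2.20 and 16.6 ± 1.34 CPM (0.276). PSTPIP2, an actin-associated adaptor, measured 1.76 ± 0.101 and 0.674 ± 0.158 CPM (0.186).

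**Figure D2:**
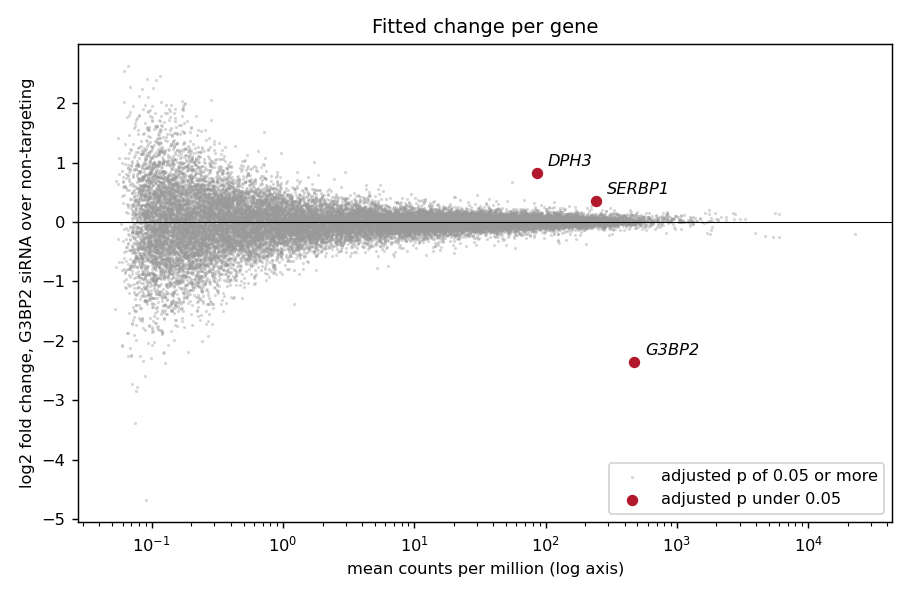
Fitted log2 fold change (G3BP2 siRNA over non-targeting) against mean CPM on a log axis, 1 point per gene, without genes of chromosome Y and XIST. Red points are the genes with an edgeR adjusted p under 0.05: DPH3 (0.82) and SERBP1 (0.35) above 0, and G3BP2 (-2.36) below.

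Of 50 stress granule protein genes, 1 rose (SERBP1), 0 fell and 49 did not pass the test, with 1 passing when adjusted over the list alone. The list was not called as a whole (median log2 fold change 0.02, camera adjusted p = 0.427). YBX1, an mRNA-packaging protein, had a log2 fold change of 0.16 (SE 0.05), and PABPC1, a poly(A)-binding protein, had 0.13 (SE 0.05), each with an edgeR adjusted p of 0.998. No member of the tau list passed the edgeR test among all genes or adjusted over the list alone: 0 of 43 genes for tau, its kinases, its phosphatases and its chaperones, with 1 at an unadjusted p under 0.05. The list's median was -0.02 (camera adjusted p = 0.759). CDK5R1, the p35 activator of the tau kinase CDK5, had a log2 fold change of -0.14 (SE 0.05, adjusted p = 0.998). The tau gene MAPT, chosen after its values were seen because tau is named in the title of the series, measured 532.8 ± 35.5 and 539.4 ± 24.1 CPM. Its 95% interval ran from -0.11 to 0.15 on the log2 scale. Of 28 tested risk genes for Alzheimer disease and frontotemporal dementia, 0 passed, and the list's median was -0.06 (camera adjusted p = 0.311). The transcription factor MEF2C of that list had a log2 fold change of 0.22 (SE 0.08).

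Genes of synapses, channels and axons showed no call over all genes tested. The 43 genes of the glutamatergic synapse had a median of -0.02 (camera adjusted p = 0.969). The NMDA receptor subunit GRIN2B measured 0.25 (SE 0.07) on the log2 scale, and the metabotropic receptors GRM7 and GRM5 measured -0.25 (SE 0.07) and 0.30 (SE 0.10). Among 44 genes of the presynaptic vesicle machinery (median -0.02, camera adjusted p = 0.459), 1 passed when adjusted over the list alone. It was SYT2, a calcium sensor of vesicle release, with a log2 fold change of -0.30 (SE 0.07). The vesicle protein SV2C measured -0.26 (SE 0.10). The 46 voltage-gated channel genes had a median of -0.03 (camera adjusted p = 0.427), with the sodium channel SCN1A at 0.13 (SE 0.06). The 46 axon guidance genes had a median of 0.06 (0.372), with the ephrin receptors EPHA5 and EPHB1 at 0.16 (SE 0.06) and 0.19 (SE 0.08). Of 42 microtubule and neurofilament genes, 33 lay above 0, with a median of 0.05 and a camera adjusted p of 0.052, and the list was called higher without non-targeting replicate 3 (0.0192) or G3BP2 siRNA replicate 2 (0.0495). It was also called with voom (0.000224), the stricter filter (0.032), the 7SL share as a covariate (0.00405) and ranks (0.0113). In that list STMN2, a regulator of microtubule dynamics in axons, and TUBA1A, an alpha-tubulin, each measured 0.15 (SE 0.07).

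Activity-regulated genes, many of them immediate early genes that neurons transcribe within minutes of activity, were lower as a list after G3BP2 siRNA. The list is named after its immediate early genes below. Of 33 tested members, 27 lay below 0 and the median log2 fold change was -0.23 (camera adjusted p = 1.26e-05). The call was lost with the correlation between members estimated from the data (adjusted p = 0.81 with an estimated correlation). None passed among all genes, with 13 at an unadjusted p under 0.05 in edgeR and 1 called by DESeq2 (FOSL2), and 3 passed when adjusted over the list alone. The 3 were FOS, FOSL2 and DUSP1, with log2 fold changes of -0.38 (SE 0.09), -0.55 (SE 0.13) and -0.25 (SE 0.07). PCSK1, a protease that processes neuropeptide precursors, measured -0.19 (SE 0.07). The list's mean stood 0.29 above the non-targeting average in non-targeting replicate 3, against -0.16 and -0.14 in the other non-targeting libraries. In the G3BP2 siRNA libraries it stood at -0.13, -0.23 and -0.30, so the groups overlapped here too. Much of the shift rests on non-targeting replicate 3, without which the camera adjusted p was 0.0192.

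Ribosomal protein and respiratory chain genes were higher as lists. Of 78 cytosolic ribosomal protein genes, 75 lay above 0, with a median log2 fold change of 0.11 (camera adjusted p = 2.13e-10). This call and the calls of both respiratory chain lists were lost with the correlation estimated (adjusted p = 0.81 with an estimated correlation for each). RPSA and RPL11 measured 0.20 and 0.15 (SE 0.05 each). Ribosomal protein genes have many processed copies that could share their reads. Of 67 nuclear-encoded subunits of the respiratory chain, 54 lay above 0, with a median of 0.08 (0.000756). ATP5PB, of ATP synthase, and COX6B1, of cytochrome c oxidase, measured 0.14 (SE 0.05) and 0.15 (SE 0.06). All 13 respiratory chain genes of the mitochondrial genome lay above 0, with a median of 0.14 (0.000756), and MT-ND5, MT-ATP6 and MT-CO1 measured 0.20 (SE 0.07), 0.23 (SE 0.08) and 0.12 (SE 0.05). The mitochondrial share of all counts was 0.385, 0.37 and 0.392% in the non-targeting libraries and 0.402, 0.436 and 0.401% in the G3BP2 siRNA libraries. In these 3 lists 0 members passed the edgeR test, over all genes or adjusted over the list alone, with 27, 6 and 4 at an unadjusted p under 0.05 and 0 called by DESeq2. The groups overlapped in each list: relative to the non-targeting average, the ribosomal mean stood at 0.11 in non-targeting replicate 3 and 0.06 in G3BP2 siRNA replicate 2. The nuclear-encoded mean stood at 0.025 and 0.008 in these libraries, and the mitochondrial mean at 0.05 in non-targeting replicate 1 and 0.03 in G3BP2 siRNA replicate 3. The nuclear-encoded list also lost its call without non-targeting replicate 2 (0.114) or G3BP2 siRNA replicate 3 (0.0901), and the mitochondrial list without G3BP2 siRNA replicate 2 (0.0987).

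**Figure D3:**
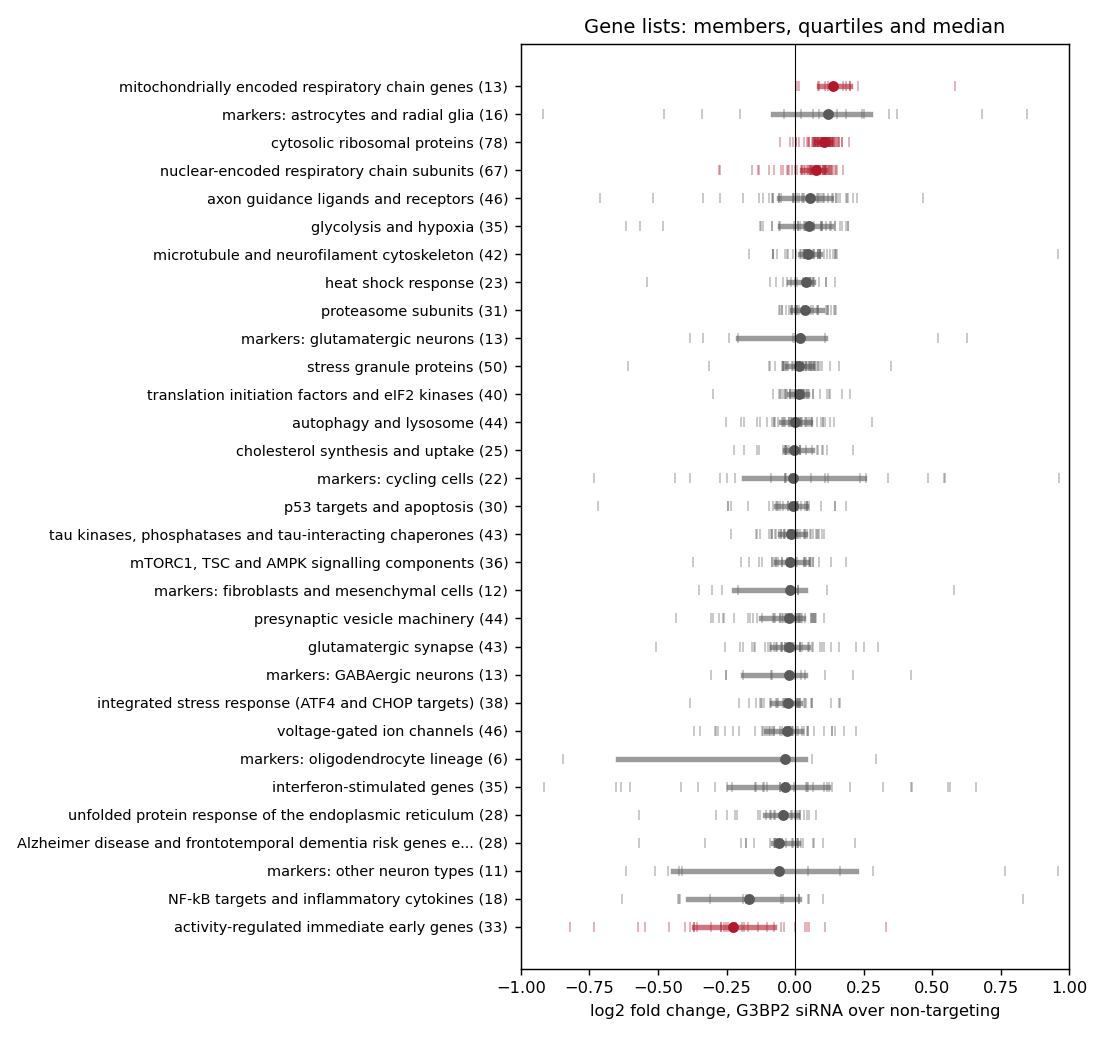
Log2 fold changes (G3BP2 siRNA over non-targeting) of the members of the 31 gene lists tested, with the number of members in parentheses. Ticks are genes, bars span the quartiles, dots are medians, red marks a camera adjusted p under 0.05, and 7 members lie beyond the axis; immediate early genes have the lowest median (-0.23) and mitochondrially encoded genes the highest (0.14).

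The stress response lists were not called in the main test, and 0 of their members passed over all genes tested. The median was -0.03 for 38 integrated stress response genes (camera adjusted p = 0.914), -0.04 for 28 unfolded protein response genes (0.0853) and 0.04 for 23 heat shock genes (0.759). Single libraries turned the direction of the integrated stress response list, which was called lower without non-targeting replicate 1 (0.00772) and higher without non-targeting replicate 3 (0.0275). The unfolded protein response list was called lower without non-targeting replicate 2 (0.0254) or G3BP2 siRNA replicate 2 (0.0495), with voom (0.0119), with the stricter filter (0.032) and with the 7SL share as a covariate (0.00405). DNAJC3 and SYVN1, which act in the endoplasmic reticulum on unfolded proteins, measured -0.21 (SE 0.07) and -0.29 (SE 0.11), and the HSP90 co-chaperone AHSA1 measured 0.11 (SE 0.05). CRYAB, the heat shock member with the smallest p, measured -2.85 (SE 0.83) at a low level. It stood at 0.1345 CPM with the non-targeting siRNA and 0.0181 CPM with the G3BP2 siRNA. For 35 interferon-stimulated genes the median was -0.04 (0.523), with B2M at -0.41 (SE 0.13) and STAT2 at -0.15 (SE 0.06). For 18 NF-kB targets it was -0.17 (0.105), and for 30 p53 target and apoptosis genes -0.01 (0.759), with the proapoptotic gene HRK at -0.23 (SE 0.10).

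Metabolic, degradation and translation factor lists were also not called in the main test. The median was 0.05 for 35 genes of glycolysis and hypoxia (camera adjusted p = 0.0853), with the glycolytic enzyme PGAM1 at 0.19 (SE 0.05) and the histone demethylase KDM3A at 0.17 (SE 0.06). HK2 of that list measured 1.51 (SE 0.44) at a low level, 0.3727 CPM with the non-targeting siRNA and 1.065 CPM with the G3BP2 siRNA. That list was called higher without non-targeting replicate 3 (0.0192) or G3BP2 siRNA replicate 2 (0.0126), with voom (0.00588), with the stricter filter (0.032) and with the 7SL share as a covariate (0.00458). It was -0.004 for 25 cholesterol genes (0.776). It was 0.04 for 31 proteasome subunits (0.101, called higher with voom at 0.0119), with PSMB4 at 0.14 (SE 0.05), and 0.01 for 40 translation initiation factors and eIF2 kinases (0.463). EIF2S1, the alpha subunit of eIF2, and EIF3I, a subunit of eIF3, measured 0.20 and 0.17 (SE 0.05 each). The 36 mTORC1, TSC and AMPK genes had a median of -0.02 (0.95), and the 44 autophagy and lysosome genes had a median of 0.00 (0.759).

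No list of cell type markers was called. The median was 0.02 for 13 glutamatergic markers (camera adjusted p = 0.87), with CUX2 at -0.24 (SE 0.07). It was -0.02 for 13 GABAergic markers (0.759), with ERBB4 at 0.42 (SE 0.18), and -0.06 for 11 markers of other neurons (0.95). Among 16 markers of astrocytes and radial glia (median 0.12, 0.463), 1 passed when adjusted over the list alone, which was NES at -0.20 (SE 0.05), while PTPRZ1 measured 0.25 (SE 0.10). The medians were -0.04 for 6 oligodendrocyte lineage markers (0.744), -0.01 for 22 cycling cell markers (0.759) and -0.02 for 12 fibroblast markers (0.969). Markers of microglia and of pluripotent cells had 3 tested members each, with medians of -0.03 and 0.13, too few for the list test. In 8 of the 31 lists tested the median, the mean and the direction of the test differed in sign. These were the glutamatergic synapse, heat shock, autophagy, cholesterol, glutamatergic marker, other neuron, cycling and fibroblast lists, none of which was called. The libraries differed in their share of 7SL RNA, the abundant RNA of the signal recognition particle: 2.32, 4.75 and 5.55% of counts with the non-targeting siRNA and 5.24, 2.09 and 3.4% with the G3BP2 siRNA.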

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

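The halved counts and the 7SL covariate were chosen after seeing the data; the other settings were fixed before the data were examined. The log2 fold change of G3BP2 stayed between -2.50 and -2.24 over the fits without 1 library. It missed the adjusted threshold in 4 of those 6 fits, which hold fewer samples, and with RLE factors (-2.37). Genes changed, 3 in the main test, numbered 1 with RLE factors (1 higher, 0 lower, 1 at 1.5-fold), 19 with DESeq2 (12, 7 and 7), 50 with no filter on low counts (24, 26 and 10) and 104 with the 7SL covariate (59, 45 and 8). The number higher was 1 with upper quartile factors, with the stricter filter and with the replicate block. Without 1 library the totals ran from 1 to 18, with 1 to 14 higher, 0 to 4 lower and 1 to 2 at 1.5-fold. The lowest total came without non-targeting replicate 2 or G3BP2 siRNA replicate 3, and the highest without non-targeting replicate 1. Lists called, 4 in the main test, numbered 8 with voom, 7 with the stricter filter, 7 with the 7SL covariate, 0 with an estimated correlation, 0 with fry, and 3 to 7 without 1 library, the highest without non-targeting replicate 3. The cause of these moves was not tested. DPH3 passed in each setting run. The labels do not say whether equal replicate numbers share a culture, and the values showed no sign of it. Deviations of same-numbered libraries correlated at -0.11, -0.01 and 0.0072, and those of other pairs at -0.1 to 0.11. With the replicate block 2 genes were called, DPH3 and G3BP2 (log2 fold change -2.38), and 4 lists. Over 52 of the other genes named, 723 values kept their direction and side of the threshold, 46 newly passed it, 8 no longer passed and 3 reversed. The 3 were of MAPT, which ran from -0.029 to 0.072 over the fits without 1 library and was below 0 without non-targeting replicate 1 or 2 or G3BP2 siRNA replicate 1. Depth limits genes of low count. In the simulation, with spread from the trend alone, 36% of all 1.5-fold changes were called against 92.9% at 10 CPM or more.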

Other observations

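The tests chosen only after the result was seen were the matched random lists, the test of G3BP2 loss acting on carriers, the comparison of covariate orders with the real one, the comparison of carriers outside the 3' UTR, the comparison of the shuffles with the other splits, and the counts of carriers among the strongest genes. The other tests were set before their result was seen.

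Some of the genes that were higher after G3BP2 siRNA carry a short sequence in their 3' UTR. Of 15929 7-mers searched in 11498 genes, CGACTAA had the highest score towards higher levels (z = 5.22), and 113 genes (0.983%) carry it. Larger scores lay in the other direction, where A/T-rich 7-mers led: TATTTTT, carried by 6216 genes, scored -6.16 and ATATTTT scored -6.15. Among the 10 higher genes with the smallest p, 5 carry CGACTAA: DPH3, SERBP1, POLE3, OXSR1 and PBX3. It is carried by 11 of the 50 higher genes with the smallest p, 13 of the 200, and 0 of the 50 lower genes with the smallest p; the 7-mer was chosen on this ranking, so these counts describe it and do not test it. The site lies in the 3' UTR of DPH3 at 16258455 to 16258461 on chromosome 3, of SERBP1 at 67413124 to 67413130 on chromosome 1, of POLE3 at 113408557 to 113408563 on chromosome 9, and of OXSR1 at 38255250 to 38255256 on chromosome 3. Only DPH3 and SERBP1 of these 5 genes passed the edgeR test over all genes. OXSR1, a stress-responsive kinase, measured 102.8 ± 5.68 and 129.6 ± 5.92 CPM, and the homeobox gene PBX3 measured 83.2 ± 3.46 and 102 ± 2.58 CPM. SYNDIG1, at rank 19 among the higher genes, also carries CGACTAA in its 3' UTR.

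Shuffling the genes' values with the search repeated gave a score as high in 0 of 1000 shuffles (highest 5.06), but 6 of the 9 other splits of the libraries passed that highest score too, so shuffles that treat genes as independent do not settle chance over the 7-mers searched. Regrouping the libraries does not exclude chance either. Of the 10 splits, the real one included, 6 had a 7-mer scoring as high, up to 9.24 against 5.22. In the other splits those were other 7-mers. CGACTAA itself scored 2.93 to 4.21 in the other splits where the libraries set as controls were mostly non-targeting. It scored -1.62 to -0.15 where they were mostly G3BP2 siRNA libraries. The 7-mer was chosen on the real split, which these splits share in part, so the signs describe it and do not test it. The score was taken after regression on 3' UTR length, GC content and expression, and carriers lay 0.0606 ± 0.0132 (SE) above genes matched on these properties, but the 7-mer was chosen on these same values, so the properties stay open. Seed pairing of a small RNA of the non-targeting pool stays open too. Carriers with an unadjusted p of at least 0.01 lay 0.0272 ± 0.0079 above matched genes (permutation p = 0.00471). That met the prediction set for seed pairing, but the 7-mer was chosen on values that include those of these carriers. A set of 151 genes with the 7-mer only in coding or 5' sequence, not counted as carriers in the search, lay 0.0324 ± 0.0085 above matched genes (permutation p = 0.00024). That permutation also treats genes as independent, and these genes were neither scored in the other splits nor matched on coding length. The value therefore does not settle whether the shift extends beyond 3' UTR carriers. These values do not tell seed pairing from another effect of the sequence, and the siRNA sequences are not given in the sources used here. With 0 libraries that received neither siRNA, loss of G3BP2 acting on carriers cannot be told apart from an effect of the non-targeting siRNA.

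The 4 lists called with the preset correlation lost their calls with an estimated correlation (adjusted p = 0.81 for each) and with fry (0.48 to 0.507). Their medians lay outside the middle 95% of the medians of 10000 random lists matched on length, GC content and expression. The percentile was 100 for ribosomal proteins, 100 for nuclear-encoded and 99.88 for mitochondrially encoded respiratory chain genes, and 0 for immediate early genes. Matched genes thus shifted less than the members of the lists. The random lists drew genes independently, while members of the lists correlated at an estimated 0.135 to 0.357. How close the matches were was not measured, so these properties are not excluded as the cause. In the 10 splits of the libraries the real one called 4 lists and each of the others 1 to 3, and 10 splits are too few for a share under 0.05. Regrouped libraries thus also gave list calls with the preset correlation. The smallest list p elsewhere was 4.62e-08 against 6.89e-12 for ribosomal proteins (1 of 10 splits as small), 4.3e-05 against 8.13e-07 for immediate early genes (1 of 10) and 0.000275 against 8.44e-05 for the mitochondrial genome (1 of 10). For nuclear-encoded subunits 2 of 10 splits were as small (1.12e-05 against 9.75e-05), so chance is not excluded there, and a response to G3BP2 loss stays open for the 4 lists. Since each library received an siRNA, another effect of either siRNA cannot be told apart from that response.

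The share of 7SL RNA may follow a structure of the libraries that cuts across the siRNA groups. The split that set non-targeting replicate 1 with G3BP2 siRNA replicates 2 and 3, the libraries with the lowest shares, called 476 genes where the siRNA groups called 3, so 2 of the 10 splits called as many and chance is not excluded for that count. With the share as a covariate the siRNA comparison called 104 genes, which included the 3. A gain from any covariate fitted to 6 libraries is not excluded: 3 of 60 orders of its values, the real one included, called as many, while the other 57 called 21 or fewer, and the 2 random orders that did (215 and 179 genes) correlated at 0.739 and 0.992 with the real order within groups, but 9 orders with fewer calls had absolute correlations of 0.739 or more, up to 0.844. Among splits fitted with the same covariate 1 of 10 called as many (highest other 20), too few splits for a share under 0.05, and no biological explanation of the 7SL share was tested.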
